A study of Homo sapiens with 42 samples.

How the data were processed

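The labels of the series describe 42 small RNA sequencing samples in 14 groups of 3: THP-1 cells (con, A4, A7, E4 and G8) and HEK293T cells given 200 nM of a control oligonucleotide (labelled mock) or one against POLR3G, each with and without end repair. Per the labels, small RNA was enriched with the mirVana PARIS kit, an extraction they describe for THP-1. Whether HEK293T cells were extracted in the same way was not established. The labels also give treatment or not with Antarctic phosphatase and polynucleotide kinase (plus or minus PNK), and libraries made with the NEBNext Small RNA kit. The count table holds columns for 30 of these samples, 10 groups of 3. The 12 samples labelled con or given the POLR3G oligonucleotide are not analysed here, and so the comparisons of A4, A7, E4 and G8 with con, and of the oligonucleotides with each other, were not run.

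The deposited values are raw counts of reads per annotated feature, with no normalization: they are whole numbers, and their column sums differ. Per the submitters' processing notes, the reads were trimmed with Trim Galore, checked with FastQC, aligned with Bowtie2 2.3.5.1 to GRCh38, and handled with SAMtools 1.9, deepTools 3.2.1 and bedtools 2.28.0. How reads with several alignments, strands and overlapping features were treated is not given in the sources used here, and was checked on the values. In 561 of 561 cases (100%) a row on the opposite strand that contains a small RNA had at least its count, so counts ignore strand and a read is counted in every row it overlaps. MIR142, for example, had 365713 counts and the rows over it on the other strand 366456 to 368070. The 16 copies of RNA5S8 had 94656 to 95545 counts each, so near-identical copies share reads and a single copy of a tRNA, snaR or pseudogene is uncertain.

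Of 175946 rows, 85931 that do not overlap were kept, small structured RNAs first, so that a read is counted near once; 155223 rows carry only a long non-coding RNA annotation. The kept rows sum, in units of 1e+06, to 9.66 to 13.3 counts per library without PNK and 5.35 to 7.72 with it, against 177 to 239 and 36.2 to 64.6 over all rows, where a read is counted 17.7 to 21.2 and 6.73 to 9.85 times. The 10 most abundant features hold 34.7% to 49.4% of counts without PNK and 35.6% to 56.0% with it. The biological coefficient of variation was 39.2% without PNK and 24.2% with it.

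Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, TMM factors of 0.515 to 1.35 without PNK and 0.797 to 1.32 with it, filterByExpr, Benjamini-Hochberg threshold 0.05). CPM values use the TMM factors and log2 CPM a prior count of 2. Each arm was fitted alone over 15 libraries for the comparisons with the libraries labelled mock (1825 and 9180 features tested, holding 99.9% and 99.4% of counts), over the 12 THP-1 libraries for the test across A4, A7, E4 and G8 and its pairs (1778 and 8562 features), and over 6 libraries for plus against minus PNK (8185 features). The design planned 15 THP-1 libraries with con in the test across groups.

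Counts were also summed over RNA families with at least 30 counts and tested in the same model, adjusted over the 23 families of a comparison, because copies within a family share reads. A family and its pseudogenes can share reads too, and their sums stay uncertain to that extent. The families are nuclear tRNA, 5S rRNA, vault RNA, Y RNA, 7SL, 7SK, U6, U6atac, RPPH1, RMRP, snaR, pseudogenes of Y RNA, 7SL, 7SK and U6, mitochondrial tRNA and rRNA, Pol II snRNA, C/D and H/ACA snoRNA, scaRNA, miRNA, and 18S, 28S and 5.8S rRNA. The interaction of group and arm was tested on the sums over the THP-1 groups. Lists were fixed by symbol and tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one. They hold these families and miRNA of haematopoietic cells, monocyte-macrophage maturation, cycling cells, epithelial cells, fibroblasts and let-7. In lists of near-identical copies, such as 5S rRNA, tRNA, snaR, U6 and pseudogenes, members share reads. Counts of members called in those lists are therefore not independent evidence. POLR3G, POLR3GL, the other Pol III subunits, histone, interferon and stress mRNAs have no rows, and BC200 is near 0.

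The genes named follow a rule: members of the small Pol III families, and the 5 largest rises and falls per comparison among features past the threshold, at or above the median abundance, whose 3 libraries of one group all lie beyond the 3 of the other (chance gives such a separation in 10% of cases). Near-identical copies count once. SNORA47, SNORD70, SNORD3A, SCARNA20, tRNA-Val-CAC-7-1 and the values of MIR142, MIR155 and MIR223 per library were picked after their values were seen. A group at 0 was set to a floor of 3 counts over the group for a lower bound.

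Whether the replicate numbers pair the libraries was checked on the residuals: all 3 correlations of same-numbered libraries exceeded 0.1 for A7 and mock (0.15 to 0.49), A4 and E4 (0.41 to 0.74) and A4 and G8 (0.11 to 0.47) without PNK, and for no other pair of groups in either arm. Other groups correlated negatively by number without PNK, such as A4 and mock (-0.77 to -0.42) and E4 and mock (-0.68 to -0.3). The residuals of a group sum to 0, so these correlations are not independent, and a pairing is not established. For the 3 pairs of groups over 0.1, a fit with replicate number as a block is given where it changes a call. That block gives every group of the fit the same effect per number.

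The procedure was tested on simulated data with 200 changed features. Copies were made of the comparisons with the libraries labelled mock, of the tests across groups, and of plus against minus PNK. The pairs of THP-1 groups were not simulated, and splits between libraries of a group were not built in. Of 4-fold changes it recovered 69.7% to 87.9% in the comparisons with the libraries labelled mock and across groups, and 30.3% in plus against minus PNK. For 2-fold changes these values were 6.06% to 36.4% and 7.58%. Of 1.5-fold changes it recovered 0% to 8.82%. Changes of 1.5-fold in single features were thus seldom recovered at this depth and spread. With the Y RNA pseudogenes raised by 1 log2 unit in A4 without PNK, their edgeR sum was recovered at 1.14. Camera with the preset correlation called 2 of 23 lists there, the raised one included, so an unchanged list was called too.

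The alternatives were DESeq2 1.42.0, DESeq2 size factors, library totals, TMM factors from miRNA alone, no filter on low counts, every deposited row, a fit of 6 libraries alone, the replicate block, leaving out each library, and leaving out G8 libraries 1 and 2. The comparisons and alternatives for the tests across groups, plus against minus PNK, the family sums and the lists were chosen before the data were examined, except those named next. The comparisons with the libraries labelled mock, the counts of the pairs, sums of tRNA isotypes with at least 300.0 counts, every deposited row, the removal of G8 libraries 1 and 2 and all alternatives for the comparisons with the libraries labelled mock and for the interaction were chosen after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.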

Results

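Small RNA was sequenced with and without phosphatase and kinase treatment (PNK), which repairs RNA ends so that fragments with blocked ends can be ligated. Counts for 30 libraries were compared, 3 per group and arm: the THP-1 groups A4, A7, E4 and G8, and the libraries labelled mock, which the labels describe as HEK293T cells given a control antisense oligonucleotide. POLR3G and POLR3GL are alternative subunits of RNA polymerase III (Pol III), and the labels do not say which of the pair was targeted in which THP-1 group, so the groups are kept apart. Neither gene has a row in the count table, and so the loss of either subunit is not measured here. The p-values measure only the spread between these libraries.

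Without PNK the libraries labelled mock were mostly C/D snoRNA, at 72.1 ± 1.96% of counts (mean ± SD, n = 3), and miRNA, at 17.2 ± 2.44%. With PNK those shares were 9.50 ± 3.79% and 0.391 ± 0.0322%, and 18S, 28S and 5.8S rRNA held 35.9 ± 5.37% against 4.02 ± 1.10% without. Nuclear tRNA was 11.1 ± 3.81% with PNK and 3.04 ± 1.09% without. Mitochondrial rRNA was 6.41 ± 0.388% against 0.113 ± 0.0253%, mitochondrial tRNA 3.97 ± 0.781% against 0.337 ± 0.141%, and 7SK 0.536 ± 0.0562% against 0.0172 ± 0.00503%. Features outside the named families made up 26.2 ± 2.34% with PNK and 1.10 ± 0.0940% without, and rows annotated only as long non-coding RNA held 59.7 ± 3.99% and 54.8 ± 14% of those counts. These comparisons ask what end repair adds to the RNAs that can be read.

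**Figure D1:**
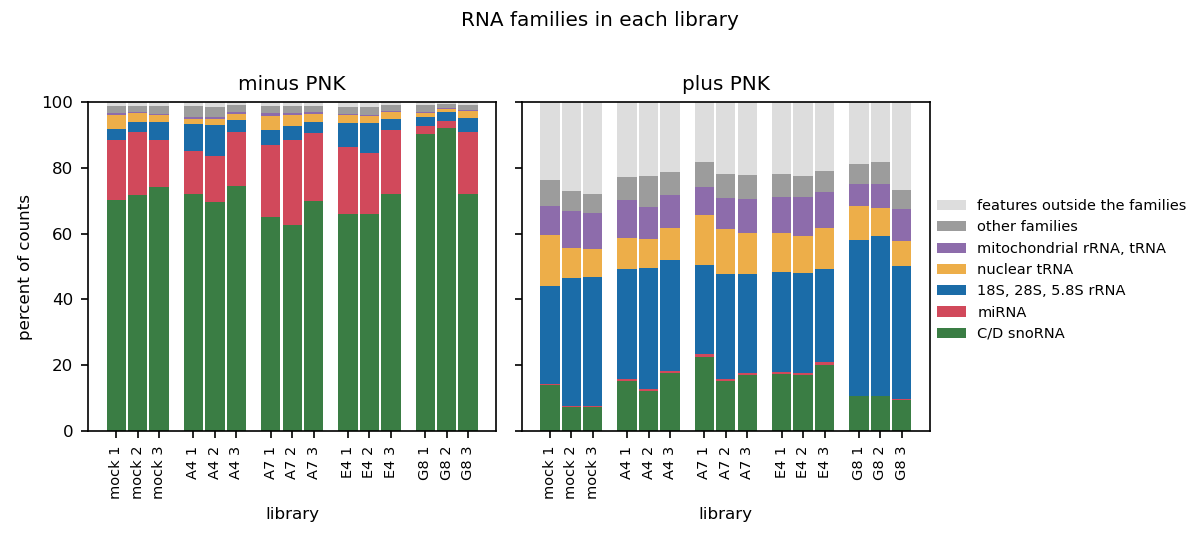
Percent of counts held by RNA families (stacked colours) in each library, minus PNK on the left and plus PNK on the right. In the libraries labelled mock C/D snoRNA falls from 72.1% to 9.50% on average, and G8 libraries 1 and 2 hold 2.16% and 2.07% miRNA without PNK.

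Because so much of the library is replaced, the scaling decides many directions between the arms: the median of all features lies 2.57 log2 units higher with PNK after TMM scaling, moves up by a further 0.91 with DESeq2 factors and 3.80 with library totals alone, and by 8.27 with factors from miRNA alone. The edgeR test called 6432 of 8185 features, 5047 higher and 1385 lower (6580 at an unadjusted p under 0.05). The split was 6313 higher and 1244 lower of 7557 with DESeq2 factors, 7211 and 730 of 7941 with library totals, and 7854 and 122 of 7976 with miRNA factors. Leaving out minus-PNK library 2 gave 5134 calls.

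Mitochondrial rRNA was higher with PNK with TMM, library totals and miRNA factors (log2 1.76, SE 0.262, adjusted p = 0.000114 with TMM, edgeR on the family sum). The miRNA sum was lower with TMM (log2 -9.53, SE 0.375, adjusted p = 2.92e-09) and with library totals. miRNA factors cannot test that sum, since they set the typical change of miRNA itself to 0. The sums of C/D snoRNA (log2 -6.96, SE 0.429), scaRNA (-5.85, SE 0.420), H/ACA snoRNA (-5.22, SE 0.576) and RMRP (-5.20, SE 0.330) were lower with TMM and with library totals, and turned to 1.79, 2.89, 3.48 and 3.6 with miRNA factors. 7SK rose by 0.90 (SE 0.257, adjusted p = 0.00775) and U6 by 0.66 (SE 0.231, adjusted p = 0.0209) in edgeR. Those calls ended with every deposited row counted (0.32 and 0.06), 7SK without minus-PNK library 2 (adjusted p = 0.0557), and U6 without minus-PNK library 1 (0.0590) or 2 (0.0608). Nuclear tRNA (-2.16), 5S rRNA (-2.26), 7SL (-1.08), Y RNA (-3.28), Y RNA pseudogenes (-3.14), snaR (-3.74), 18S, 28S and 5.8S rRNA (-0.92), Pol II snRNA (-1.26), 7SL pseudogenes (-0.88) and U6atac (-1.35) were lower with TMM. All of these turned higher with library totals and with miRNA factors, so no direction is claimed for them. Their calls also depend on single libraries for rRNA (adjusted p = 0.0615, 0.115 and 0.0874 without plus-PNK library 1, 2 or 3), 7SL (0.0891 and 0.0835 without plus-PNK library 2 or 3), 7SL pseudogenes (0.0728 without plus-PNK library 3) and U6atac (0.0643 without minus-PNK library 1).

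Among single RNAs, MIR660 and MIR195 had no counts with PNK and were at least 1410-fold and at least 1220-fold lower with TMM (floor of 3 counts over the group). Such floors cover counting error only, and the upward shifts of 3.80 and 8.27 log2 units with library totals and miRNA factors would make these bounds far smaller. Row lnc-LUC7L2-3, which lies over the pseudogene ERHP1, was at least 19.7-fold higher with PNK by TMM. RNY1 (log2 -4.37), RNY5 (-4.31) and VTRNA1-3 (-4.75) fell with TMM, and library totals ended those calls at -0.25, -0.22 and -0.68. RNY4 (-2.93), RNY3 (-1.98), VTRNA1-1 (-1.50) and VTRNA1-2 (-2.53) turned to 1.16, 2.11, 2.55 and 1.54 with library totals; nc886 (VTRNA2-1) was not called (log2 -0.38, SE 0.424, adjusted p = 0.400). Of the lists fixed beforehand, 274 of 314 miRNA were lower and 23 higher (297 called when adjusted over the list alone), and all 17 of 17 scaRNA were lower. Camera with an estimated correlation gave adjusted p = 0.0368 for both lists, 0.0429 for the 13 monocyte-macrophage miRNA, and 0.0758 for the 9 cycling-cell and the 6 haematopoietic miRNA. The 3 epithelial and 4 fibroblast miRNA were called by camera (9.56e-05 and 3.4e-06) and missed with an estimated correlation, at 0.0866 and 0.0778.

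Without PNK the libraries labelled mock hold miRNA of blood cells at the level of A4, A7 and E4. G8, whose libraries differ, is left out here. MIR142, a haematopoietic miRNA, stood at 2680 ± 808 CPM (counts scaled by library size) without PNK in them, against 1986 ± 482 in A4, 2571 ± 479 in A7 and 2138 ± 176 in E4. MIR155 was 3258 ± 302 and MIR223 413 ± 49.0 in the libraries labelled mock, and neither they nor MIR142 was called against A4, A7 or E4. The 7 haematopoietic miRNA tested without PNK lay -0.72 to 0.72 log2 units from the mean of those groups. With PNK most of those tested, and the miRNA sum, were higher in A4, A7 and E4 than in the libraries labelled mock with TMM scaling. The comparisons of A4, A7, E4 and G8 with the libraries labelled mock follow the labels. By the labels they cross cell lines, which the miRNA values without PNK do not show. They share 3 mock libraries per arm, so their results are not independent of each other.

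What differs among the THP-1 groups themselves was asked with an edgeR test across A4, A7, E4 and G8. Without PNK, nc886 (VTRNA2-1, chromosome 5, 136080497 to 136080597), a Pol III transcript, stood at 888 ± 363 CPM in A7 against 176 ± 26.3 in A4, 155 ± 15.5 in E4 and 263 ± 96.6 in G8. It differed among the groups (adjusted p = 0.00263), and did so without each of the 12 libraries. SNORA47 ran from 134 ± 110 CPM in A4 and 25.0 ± 21.1 in E4 to 3.40 ± 1.49 in A7 and 2.91 ± 2.41 in G8 (adjusted p = 0.0111). MIR363, from a miRNA cluster on X, was 246 ± 82.2 CPM in A4, 57.8 ± 8.51 in A7, 20.3 ± 2.22 in E4 and 16.3 ± 22.2 in G8 (adjusted p = 0.0116). SNORD70 was 2543 ± 1040 CPM in G8 and 385 ± 116 in A7 (adjusted p = 0.00476). The test called 575 of 1778 features (864 at an unadjusted p under 0.05). The count was 305 and 293 without A4 library 1 or 2, 247 and 281 without A7 library 1 or 2, 339 and 354 without E4 library 1 or 2, and 363, 272 and 1296 without G8 library 1, 2 or 3. It was 646 without G8 libraries 1 and 2.

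G8 is not one profile without PNK. Its libraries 1 and 2 held 2.16% and 2.07% miRNA, and library 3 held 19%, inside the 13.1% to 25.9% of the other groups. MIR142 was 167 and 229 CPM in libraries 1 and 2 and 2510 in library 3, and MIR155 was 669.5, 1084 and 3365. C/D snoRNA took 84.9 ± 11.2% of G8 counts. Every G8 value without PNK carries that split, and the counts of calls without libraries 1 and 2 are given as well. Library 3 also lies apart in other groups. The chi-square per feature between a pair of libraries of a group, near 1 for counting error alone, was 21.7 for A4 libraries 1 and 2 but 589 and 592 for each with library 3, 45.6 against 219 and 383 in E4, and 65.5 against 396 and 308 in the libraries labelled mock. SNORA47 follows that split: with factors from all 15 libraries it was 172, 214.5 and 9.503 CPM in A4 libraries 1, 2 and 3, 27.18, 46.29 and 3.287 in E4, and 0.6684, 1.647 and 51.65 in the libraries labelled mock.

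The sum of the vault RNAs, which includes nc886, was lower in A4 than in A7 by edgeR (log2 -1.64, SE 0.277, adjusted p = 0.00225), and higher in A7 than in E4 (1.87, SE 0.279, 0.000760) and G8 (1.53, SE 0.276, 0.00195), in each case without any 1 of the 6 libraries. With factors from miRNA alone these calls ended (-1.29 and 1.92) and the difference from G8 turned to -0.71. For nc886 itself A4 against A7 gave -2.34 (SE 0.372, adjusted p = 0.0109), lost without A4 library 1 (0.0592) or 2 (0.0615). A7 against G8 gave 1.91 (adjusted p = 0.00701), which turned to -0.36 with miRNA factors. RNY1 and RNY5 were higher in A4 than in G8 (1.71, adjusted p = 0.00246, and 1.48, 0.00692), and miRNA factors moved them to 0 and -0.40. Y RNA pseudogenes were lower in G8 than in A4 (A4 minus G8 1.40, SE 0.175, adjusted p = 0.000148) and A7 (1.07, 0.00160), and miRNA factors turned both, to -0.33 and -1.01. C/D snoRNA was higher in G8 than in A7 (A7 minus G8 -1.20, SE 0.279, adjusted p = 0.00738), and library totals ended that call at -0.37.

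Pair by pair without PNK, edgeR called 214 features between A4 and A7 (132 higher in A4, 82 lower), 16 between A4 and E4 (7 and 9), 417 between A4 and G8 (276 and 141), 470 between A7 and G8 (278 and 192) and 393 between E4 and G8 (229 and 164). Between A7 and E4 it called 2 (281 at an unadjusted p under 0.05), nc886 among them (log2 2.55, adjusted p = 0.0398), and 62 with no filter on low counts, where E4 against G8 fell to 240. The nc886 call was lost with miRNA factors (0.827), without A7 library 1 (0.144) or 2 (0.120) or any E4 library (0.141 to 0.267). Without G8 libraries 1 and 2 the A4, A7 and E4 counts against G8 were 384, 80 and 125. Without A4 library 1 or 2 the A4 and A7 count was 0, and without A7 library 1, 2 or 3 it was 9, 13 and 106. The A4 and E4 count was 2 or 3 without any 1 library, and 2 with replicate number as a block, the fit that a pairing of these libraries calls for. The A7 and E4 count rose to 21 without A7 library 3 and was 0 without any other library. Without G8 library 3 the A4, A7 and E4 counts against G8 were 973, 1166 and 982. They were 256, 186 and 43 without G8 library 2 and, for A7 and E4, 221 and 94 without G8 library 1. Without A4 library 1 or 2 the G8 count was 264 and 253, without A7 library 1 or 2 it was 126 and 135, and without E4 library 1, 2 or 3 it was 58, 82 and 40.

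The direction of the G8 pairs depends on the scaling chosen. miRNA factors take up the low miRNA of G8 libraries 1 and 2, so a move of the other features is partly built into them. TMM put the median of all features 0.25, 0.25 and 0.20 higher in A4, A7 and E4 than in G8. miRNA factors moved those medians by -1.48, -1.87 and -1.88, with splits of 125 higher and 613 lower, 102 and 923, and 98 and 932. Library totals moved them by 0.31, 0.70 and 0.48. For A4 against A7, A4 against E4 and A7 against E4, library totals moved the median by -0.37, -0.15 and 0.22. miRNA factors moved the first pair of these by 0.37 and 0.40, leaving 7 calls (4 and 3) and 6 calls (3 and 3).

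With PNK, the same test among the THP-1 groups called 1890 of 8562 features (3145 at an unadjusted p under 0.05), between 1465 and 2488 without any 1 library. SNORD3A (the U3 snoRNA) was 704 ± 673 CPM in A4 on average, 189.9 in E4, 54.2 in A7 and 34.2 in G8 (adjusted p = 0.00172). SCARNA20 was 138 ± 104 CPM in A4 and 169.5 ± 135 in E4 against 28.7 in A7 and 8.38 in G8 (adjusted p = 0.0108), and SNORA47 again ran from 22.1 ± 18.2 in A4 to 0.911 in A7 and 0.638 in G8 (adjusted p = 0.00479). The tRNA copy tRNA-Val-CAC-7-1 was 480.4 ± 632 CPM in A4 and 8.85 in G8 (adjusted p = 0.00243). The large SDs in A4 show that the libraries of that group differ, and each of these calls held without any 1 of the 12 libraries.

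U6, transcribed by Pol III, was higher in G8 than in each other group with PNK, with TMM, library totals and miRNA factors: A4 against G8 gave log2 -0.86 (adjusted p = 0.00704, edgeR on the sum), A7 against G8 -1.28 (0.00164) and E4 against G8 -1.24 (0.00111). Without G8 libraries 1 and 2 the A4 call ended at -0.82 (adjusted p = 0.0719). U6 pseudogenes, which share reads with U6, were likewise higher in G8 than in A7 (A7 minus G8 -1.20, 0.00405) and E4 (-1.15, 0.00371). Mitochondrial tRNA was higher in A4 than in A7 (0.61, adjusted p = 0.00186), a call that library totals ended at 0.30 and miRNA factors at an adjusted p of 0.0518. It was also higher in A4 (0.80, 0.000146) and E4 (0.60, 0.00111) than in G8, and miRNA factors turned these to -0.40 and -0.81. The H/ACA snoRNA sum was higher in A4 than in A7 (1.35, adjusted p = 0.00526). RMRP was higher in A4 than in A7 (2.09, adjusted p = 0.00471) and G8 (1.96, 0.00505), the last ending with miRNA factors (0.89, 0.0763) or without G8 libraries 1 and 2 (0.123).

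With PNK the pairs gave 1159 features between A4 and A7 (747 higher in A4, 412 lower), 813 between A4 and E4 (511 and 302), 1291 between A4 and G8 (839 and 452), 709 between A7 and G8 (414 and 295) and 951 between E4 and G8 (536 and 415). Only 8 were called between A7 and E4 (3 and 5; 823 at an unadjusted p under 0.05), and 176 with no filter on low counts. Without A4 library 2 the A4 counts against A7, E4 and G8 were 564, 382 and 837, and A7 library 2 or 3 moved the first to 539 and 660. Without E4 library 1, 2 or 3 the A4 and E4 count was 448, 373 and 385, and without G8 library 2 the A4 and G8 count was 794. The A7 and G8 count was 344, 446 and 455 without A7 library 1, 2 or 3 and 399, 345 and 1099 without G8 library 1, 2 or 3. The E4 and G8 count was 509 and 505 without E4 library 1 or 2 and 606 and 522 without G8 library 1 or 2, and the A7 and E4 count was 2 without any A7 library and 1 without E4 library 1 or 2. Without G8 libraries 1 and 2 the A4, A7 and E4 counts against G8 were 486, 209 and 264. miRNA factors moved the medians against G8 by -1.16, -1.37 and -1.35, with splits of 258 higher and 4783 lower, 47 and 6204, and 63 and 5904, and those of A4 against A7 and E4 by 0.20 and 0.18, with 655 and 68, and 423 and 52. Library totals moved them by -0.17, 0.13 and 0.03 for A4, A7 and E4 against G8 and by -0.30 and -0.21 for A4 against A7 and E4. The A7 and E4 split was 4 higher and 24 lower with miRNA factors.

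Whether a group effect on a family depends on the arm was tested by an edgeR interaction over the 4 THP-1 groups, and 8 of the 23 family sums passed. Plus minus minus PNK, where the level common to all groups rests on the scaling, the vault sum was at log2 1.30 in E4, 0.98 in G8, 0.48 in A4 and -0.41 in A7 (adjusted p = 0.0108). RMRP went from -2.54 in A4 to -4.30 in A7 (0.0165), and 18S, 28S and 5.8S rRNA from -1.13 in E4 to 0.42 in G8 (0.0196). The count was 2 with miRNA factors, 3 without G8 libraries 1 and 2, 5 without G8 library 2 and 13 without A4 library 1.

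Against the libraries labelled mock without PNK, A4 had less of several tRNAs. The copy tRNA-Met-CAT-1-24 was 31.7 ± 4.48 CPM against 154 ± 31.9 (log2 -2.28, SE 0.337, adjusted p = 0.00607, edgeR), and tRNA-SeC-TCA-1-1, the tRNA for selenocysteine, 11.2 ± 0.526 against 62.3 ± 34.2 (-2.48, SE 0.423, 0.0154). nc886 was 176 ± 26.3 against 624 ± 268 (-1.83, SE 0.396, 0.0396). edgeR called 24 of 1825 features, 1 higher and 23 lower (306 at an unadjusted p under 0.05), and DESeq2 called 86. Of 404 tRNA, 1 was higher and 20 lower (59 called when adjusted over the list alone; camera adjusted p = 1.84e-06, and adjusted p = 0.310 with an estimated correlation). C/D snoRNA had 0 of 224 called and H/ACA snoRNA 0 of 93, with adjusted p = 0.695 and 0.621 with an estimated correlation. The 7 haematopoietic, 9 cycling-cell, 11 let-7, 13 monocyte-macrophage, 4 epithelial and 4 fibroblast miRNA also had 0 called by edgeR, though 2 of the monocyte-macrophage list when adjusted over the list alone. The 3 RNAs named were lost without any A4 library or mock library 2 (adjusted p = 0.0535 to 0.275), and tRNA-SeC-TCA-1-1 and nc886 without mock library 1 (0.0863 and 0.264). Both were also lost in a fit of the 6 libraries alone (0.0982 and 0.105) and with miRNA factors (0.216 and 0.463), and nc886 with DESeq2 factors (0.0551) and with every row counted (0.0527). The count was 0 without A4 library 1, 2 or 3 or mock library 2, 4 without mock library 1 and 44 without mock library 3. It was 5 with DESeq2 factors (1 higher, 4 lower), 71 with no filter and 6 with miRNA factors (4 higher, 2 lower), which moved the median by 0.34. Single tRNA copies share reads, so the copy named is uncertain.

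In A7 without PNK, MIR132 was 5.46 ± 0.272 CPM against 28.4 ± 1.39 in the libraries labelled mock (log2 -2.38, SE 0.427, adjusted p = 0.0360, edgeR), and tRNA-Leu-AAG-1-3 15.7 ± 0.613 against 6.88 ± 1.33 (1.19, SE 0.230, 0.0360). Both were lost without any 1 of the 6 libraries (adjusted p = 0.123 to 0.277 and 0.123 to 0.258), and at 0.0722 with replicate number as a block. The block was fitted over all 15 libraries with the same effect per number in every group. It therefore does not show what a fit of A7 and mock pairs alone would give. tRNA-Leu-AAG-1-3 was also lost with every row counted (0.111), with no filter (0.822) and with miRNA factors (0.896). MIR142 (-0.06) and MIR223 (0.13) were not called. edgeR called 7 of 1825 features, 3 higher and 4 lower (205 at an unadjusted p under 0.05), DESeq2 39, and the block 0. The count was 0 without any 1 library and 36 in a fit of the 6 libraries alone. No family sum was called. tRNA had 1 higher and 1 lower of 404 (2 adjusted over the list alone; camera adjusted p = 2.14e-10, and adjusted p = 0.0632 with an estimated correlation). Library totals moved the median by 0.28, and with TMM the median lies at -0.11.

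In E4 without PNK, MIR363 was 20.5 ± 1.55 CPM against 301 ± 71.4 in the libraries labelled mock (log2 -3.88, SE 0.747, adjusted p = 0.0145, edgeR). tRNA-Met-CAT-1-24 was 31.1 ± 1.96 against 154 ± 31.9 (-2.31, SE 0.337, 0.00368), and tRNA-Leu-AAG-1-3 rose from 6.88 ± 1.33 to 26.5 ± 3.30 (1.95, SE 0.234, 0.00143); both held without any 1 of the 6 libraries, and with miRNA factors the second was lost (0.125). MIR132 was 4.86 ± 0.151 (-2.54, 0.00895), lost without E4 library 1 (0.0638) or 2 (0.0797) or mock library 2 (0.0522). MIR363 was lost without E4 library 1 (0.105), 2 (0.101) or 3 (0.0681) or mock library 1 (0.0653) or 2 (0.0535). nc886 was 155 ± 15.5 against 624 ± 268 (-2.01, 0.0155), lost without any E4 library (0.0675 to 0.106), without mock library 1 (0.0980) or 2 (0.0535), and with miRNA factors (0.255). The vault sum (-1.37, SE 0.314, adjusted p = 0.0189) was lost without any E4 library (0.0564 to 0.0914), without mock library 1 (0.0779) and with miRNA factors (0.67). edgeR called 77 of 1825 features, 20 higher and 57 lower (321 at an unadjusted p under 0.05). The count was 12, 8 and 15 without E4 library 1, 2 or 3, 14 and 5 without mock library 1 or 2, 165 by DESeq2 and 8 with miRNA factors (2 and 6). Y RNA pseudogenes had 0 higher and 28 lower of 224 (71 adjusted over the list alone; camera adjusted p = 8.68e-07, and adjusted p = 0.359 with an estimated correlation), and the monocyte-macrophage list 2 lower of 13 (3 over the list alone; 0.927).

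In G8 without PNK, MIR132 was 2.32 ± 2.19 CPM against 28.4 ± 1.39 (log2 -3.54, SE 0.462, adjusted p = 0.000375, edgeR) and MIR363 16.5 ± 21.8 against 301 ± 71.4 (-4.17, SE 0.759, 0.00240). Both held without any 1 library, at -4.87 to -3.06 and -6.38 to -3.52, and were lost in a fit of the 6 libraries alone (0.0636 and 0.114). Each fit without 1 library keeps G8 library 1 or 2, where miRNA fell as a class (median log2 ratio to library 3 of -2.36). Such fits therefore cannot show whether the calls of these 2 miRNA rest on that fall. SNORD121B was 1466 ± 810.0 against 327 ± 26.5 (2.17, SE 0.359, 0.00129), and it too was lost in that fit (0.0950). SNORD54 (2.24, 0.00492) fell to 0.63 without G8 libraries 1 and 2. The row lnc-MS4A6A-1, with 43.5% of its length in exons of MS4A6A, fell from 2.3 to 0.69. Those 2 calls rest on that pair of libraries and were also lost in the fit of 6 (0.118 and 0.0999). edgeR called 490 of 1825 features, 197 higher and 293 lower (733 at an unadjusted p under 0.05). C/D snoRNA had 83 higher and 1 lower of 224 (100 adjusted over the list alone), miRNA 2 higher and 47 lower of 354 (27) and Pol II snRNA 18 higher and 1 lower of 37 (26), each with adjusted p = 0.525 with an estimated correlation. Without G8 libraries 1 and 2 the Pol II snRNA sum turned to -0.11. The monocyte-macrophage list had 5 lower of 13 (5), the haematopoietic list 2 of 7 (2), epithelial miRNA 1 of 4 (1), each also at 0.525, and let-7 0 of 11 and fibroblast miRNA 0 of 4 by edgeR. Y RNA pseudogenes had 3 higher and 162 lower of 224 (177; adjusted p = 0.00196 with an estimated correlation), but their sum (-1.12, SE 0.161, 0.000261) turned to 0.74 with miRNA factors. The 7SL sum rose by 1.19 (SE 0.244, 0.00255), lost at 0.62 without G8 libraries 1 and 2. The count of calls was 252, 219 and 1039 without G8 library 1, 2 or 3, 202 and 247 without mock library 1 or 2, 183 without G8 libraries 1 and 2 and 34 in the fit of 6. miRNA factors moved the median by 1.63 (886 higher, 135 lower), DESeq2 factors by 0.11 (248 and 245) and library totals by -0.53; with TMM it lies at -0.16.

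**Figure D2:**
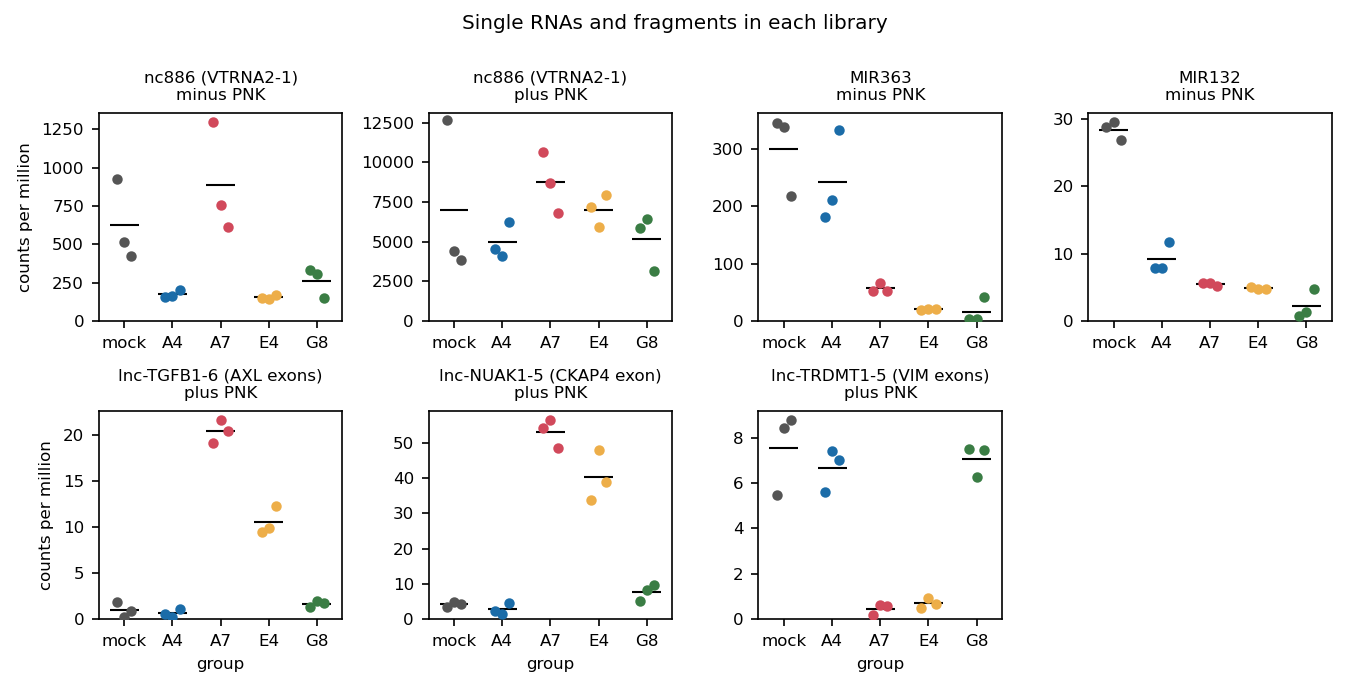
CPM in each library (points) with the group mean (line) for nc886, MIR363, MIR132 and the rows over AXL, CKAP4 and VIM. nc886 averages 888 in A7 without PNK and 155 in E4; the row over AXL averages 20.4 in A7 with PNK and 0.975 in the libraries labelled mock.

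With PNK, where fragments of longer RNAs are read, A7 and E4 differed from the libraries labelled mock at rows over 3 protein-coding genes named here. The row lnc-TGFB1-6, over exons of AXL on the other strand (chromosome 19, 41260417 to 41262385), was 20.4 ± 1.22 CPM in A7 and 10.6 ± 1.52 in E4 against 0.975 ± 0.797 (log2 4.46, SE 0.357, adjusted p = 2.21e-06, and 3.51, SE 0.370, 3.07e-05; edgeR). lnc-NUAK1-5, inside an exon of CKAP4, was 53.0 ± 4.03 and 40.1 ± 7.22 against 4.20 ± 0.673 (3.64 and 3.24). lnc-TRDMT1-5, over exons of VIM on the other strand, was 0.462 ± 0.259 and 0.70 ± 0.224 against 7.55 ± 1.81 (-3.96 and -3.39). All of these held without any 1 of the 6 libraries (lnc-TGFB1-6 at 3.94 to 5.22 and 2.99 to 4.28) and under every setting tried. The counts ignore strand, so the reads may belong to either gene of each pair.

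In A7 with PNK, edgeR called 454 of 9180 features, 295 higher and 159 lower (1611 at an unadjusted p under 0.05). snaR had 9 of 12 higher (12 adjusted over the list alone), let-7 8 of 11 (11), C/D snoRNA 53 of 203 (77) and miRNA 61 of 191 (96), with adjusted p = 0.190, 0.167, 0.167 and 0.167 with an estimated correlation. The snaR sum was higher (log2 1.58, SE 0.453, adjusted p = 0.0249), lost without A7 library 1 (0.183) or mock library 2 (0.102) or 3 (0.111), with library totals (0.0813) and with miRNA factors (0.54). Haematopoietic miRNA had 4 of 6 higher (5 over the list alone; 0.167 with an estimated correlation), cycling-cell miRNA 5 of 9 (9; 0.167), the monocyte-macrophage list 4 of 7 (5; 0.201) and epithelial miRNA 1 of 1. The count of calls was 144 and 285 without A7 library 1 or 3 and 164 and 153 without mock library 2 or 3. miRNA factors moved the median by -0.93 (39 higher, 4183 lower) and library totals by -0.25, so the share that is higher rests on the scaling.

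In E4 with PNK, edgeR called 724 of 9180 features, 496 higher and 228 lower (2020 at an unadjusted p under 0.05). C/D snoRNA had 113 of 203 higher (164 adjusted over the list alone; adjusted p = 0.0968 with an estimated correlation), tRNA 113 higher and 1 lower of 410 (193; 0.138), H/ACA snoRNA 22 of 90 (43; 0.179), and snaR 8 of 12 (12; 0.211). Mitochondrial tRNA had 9 of 20 higher (14), with adjusted p = 0.0193 with an estimated correlation, and its sum was higher by 0.50 (adjusted p = 0.00799), lost with library totals (0.14) and turning to -0.46 with miRNA factors. The scaRNA sum rose by 1.57 (adjusted p = 0.00799), lost with miRNA factors (0.58). miRNA had 62 higher and 1 lower of 191 (102; 0.138), haematopoietic miRNA 5 of 6 (5; 0.151), cycling-cell miRNA 6 of 9 (9; 0.151), let-7 4 of 11 (9; 0.203), the monocyte-macrophage list 3 of 7 (5; 0.211) and epithelial miRNA 1 of 1 higher. The count of calls was 385 and 417 without E4 library 1 or 2 and 430 and 417 without mock library 2 or 3. miRNA factors moved the median by -0.96 (88 higher, 4549 lower) and library totals by -0.35.

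In A4 with PNK, RMRP was 584 ± 376 CPM against 115 ± 34.4 in the libraries labelled mock (log2 2.34, SE 0.408, adjusted p = 0.00146, edgeR), and RNY5 1164 ± 297 against 215 ± 7.57 (2.44, SE 0.345, 4e-04). The 5S rRNA sum rose by 1.65 (SE 0.446, adjusted p = 0.00697), the H/ACA snoRNA sum by 1.59 (SE 0.267, 0.000576), the scaRNA sum by 1.82 (SE 0.372, 0.00157) and the C/D snoRNA sum by 1.16 (SE 0.336, 0.00910). All of these held without any 1 library (RMRP at 1.7 to 2.67 and 5S rRNA at 1.25 to 2.26), and the sums were lost with miRNA factors (0.84, 0.75, 1.00 and 0.27). RN7SL1 was 428 ± 544 against 62.1 ± 17.7 (2.78, 0.00733), which rests on A4 library 2 (0.87, adjusted p = 0.0514 without it) and was lost in a fit of the 6 libraries alone (0.0530). 7SK pseudogenes (2.00, SE 0.488, 0.00501) and 7SL pseudogenes (2.08, SE 0.558, 0.00697) were lost with miRNA factors (1.25 and 1.36), and fell to 0.98 and 0.68 without A4 library 2, still past the threshold. RPPH1, the RNA of RNase P (1.25, SE 0.366, 0.00910), was lost without A4 library 2 (0.0533), with library totals (0.158) and with miRNA factors (0.45). The row lnc-ZCCHC13-13, of which the pseudogene DDX3P1 covers only 17.9%, was 3.85 ± 0.433 against 16.8 ± 1.49 (-2.10, SE 0.207, 2.55e-05), and AF233439.1 1.37 ± 0.565 against 8.77 ± 0.762 (-2.72, SE 0.287, 3.91e-05). edgeR called 1022 of 9180 features, 764 higher and 258 lower (2185 at an unadjusted p under 0.05).

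Of the lists in A4 with PNK, C/D snoRNA had 138 of 203 higher (176 adjusted over the list alone), H/ACA snoRNA 70 higher and 2 lower of 90 (81) and scaRNA 15 of 19 (19), with adjusted p = 0.0414 for each with an estimated correlation. 5S rRNA had 64 of 73 higher (67; 0.0807), tRNA 160 higher and 4 lower of 410 (226; 0.0902) and miRNA 49 of 191 (83; 0.143). Haematopoietic miRNA had 5 of 6 higher (6; 0.143), cycling-cell miRNA 5 of 9 (7; 0.143), let-7 4 of 11 (7; 0.224), the monocyte-macrophage list 2 of 7 (6; 0.252) and epithelial miRNA 0 of 1. The count of calls was 593 without A4 library 2 and 569 and 664 without mock library 2 or 3. miRNA factors moved the median by -0.87 (296 higher, 3570 lower) and library totals by -0.54, and with these the sums of 18S, 28S and 5.8S rRNA (0.51) and of mitochondrial rRNA (0.50) turned to -0.34 and -0.37, and to -0.05 for both.

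In G8 with PNK, the row lnc-GEMIN6-1 was 1.42 ± 0.778 CPM against 25.1 ± 1.16 (log2 -4.25, SE 0.364, adjusted p = 4.15e-06, edgeR). Only 6.39% of that row is exon of DHX57, on the other strand, so its reads cannot be assigned to that gene. The row lnc-CCL28-2, over exons of HMGCS1, was 1.29 ± 0.752 against 11.1 ± 2.90 (-2.97, SE 0.351, 0.000121). tRNA-Arg-TCT-5-2 was 8.09 ± 2.12 against 1.24 ± 0.295 (2.64, SE 0.357, 0.000358) and tRNA-Glu-TTC-3-1 68.9 ± 20.5 against 498 ± 275 (-2.86, SE 0.367, 0.000250). All 4 held without any 1 library (lnc-CCL28-2 at -3.63 to -2.7). The U6 sum rose by 1.13 (SE 0.214, adjusted p = 0.00359), lost with library totals (0.77, 0.0589) and without G8 libraries 1 and 2 (1.09, 0.0952). The 18S, 28S and 5.8S rRNA sum rose by 0.79 (SE 0.181, 0.00862), lost at 0.19 without that pair and at 0.34 with library totals. U6 had 9 of 9 members higher (9 adjusted over the list alone; adjusted p = 0.357 with an estimated correlation), C/D snoRNA 26 of 203 (64; 0.616), and the haematopoietic, cycling-cell, let-7 and monocyte-macrophage lists had 0 called by edgeR. edgeR called 504 of 9180 features, 262 higher and 242 lower (1861 at an unadjusted p under 0.05). The count was 295, 288 and 868 without G8 library 1, 2 or 3, 257 and 269 without mock library 2 or 3, and 178 without G8 libraries 1 and 2. miRNA factors moved the median by 0.23 (234 higher, 76 lower) and library totals by -0.37.

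**Figure D3:**
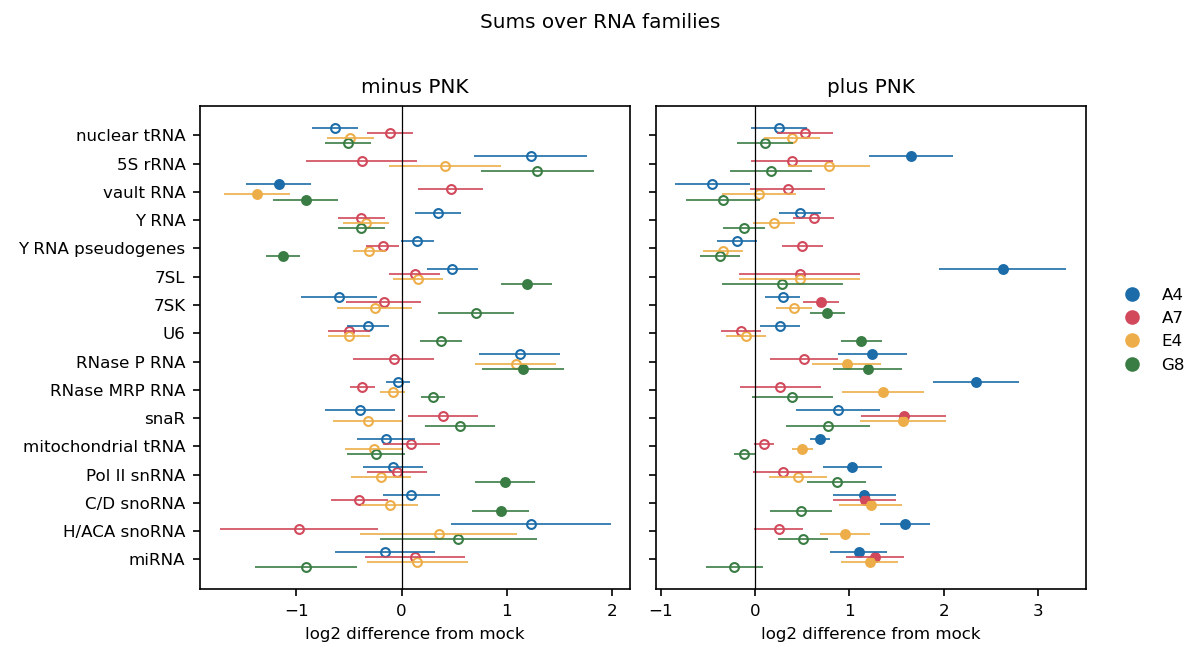
Log2 difference of RNA family sums from the libraries labelled mock (points; bars show 1 SE; filled points passed an adjusted p of 0.05), minus PNK left and plus PNK right, with TMM scaling. Vault RNA lies at -1.37 in E4 without PNK, a call lost without any E4 library, and in A4 with PNK H/ACA snoRNA lies at 1.59 and mitochondrial tRNA at 0.69, the last turning to -0.17 with factors from miRNA alone.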

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

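In this part the tests of carry-over, of a change of the G8 cells, of the minus-PNK preparation, of the nc886 interaction and of groupings within library numbers were chosen after the result was seen, as were the comparisons with the libraries labelled mock and the counts of the pairs whose splits are given.

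For 8 RNA families the effect of the THP-1 group differed between the PNK arms in an edgeR interaction test, which is what marked them for a closer look. The adjusted p was 0.00245 for U6 pseudogenes and for Y RNA pseudogenes, 0.0108 for vault RNA, 0.0165 for C/D snoRNA, mitochondrial tRNA, RMRP (RNase MRP RNA) and U6, and 0.0196 for 18S, 28S and 5.8S rRNA. Plus minus minus PNK, U6 pseudogenes were at log2 1.76 in G8 and 0.27 in A7, Y RNA pseudogenes at -1.53 in G8 and -3.20 in A4, C/D snoRNA at -6.45 in G8 and -5.14 in A7, mitochondrial tRNA at 0.65 in E4 and -0.28 in A7, and U6 at 2.31 in G8 and 1.27 in A7. With factors from miRNA alone 2 families passed, and without G8 libraries 1 and 2, 3 did, so the choice of libraries and scaling bears on this set.

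Without PNK the libraries labelled mock, which the labels give as HEK293T, hold miRNA typical of blood cells at the level of A4, A7 and E4. G8, where 2 libraries are low in miRNA, is left out of that comparison of levels. RNA from THP-1 carried over into HEK293T libraries cannot be told apart from other causes: the 7 haematopoietic miRNA lay at a median of -0.08 log2 units from the mean of A4, A7 and E4, but from -0.72 to 0.72 one by one, which leaves room for a large share. An exchange of sample names is allowed by the values, but they do not establish it. Over 352 miRNA the Spearman correlation of the mock group with the THP-1 groups was 0.937 to 0.978. Among the 4 THP-1 groups it was 0.939 to 0.990. G8 is in both ranges, and its low-miRNA libraries may set the low ends. No library known to be of another cell line was at hand to show how low its correlation would lie. The correlations are across miRNA, which are not independent replicates. All of these values are without PNK. With PNK most of the haematopoietic miRNA tested, and the miRNA sum, were higher in A4, A7 and E4 than in the libraries labelled mock with TMM scaling. No biological explanation was tested, and which samples the columns hold stays open.

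G8 libraries 1 and 2 without PNK held 2.16% and 2.07% miRNA and more C/D snoRNA than library 3 (median log2 ratio 1.37 for C/D snoRNA and -2.36 for miRNA). Preparation of the minus-PNK libraries alone is argued against by the plus-PNK libraries, where libraries 1 and 2 (0.191% and 0.149%) lie -1.55 log2 units from library 3 (0.497%), beyond the largest spread in another group, 0.69. A change of the G8 cells as a group cannot be told apart, since only library 3, at 19% miRNA, lies inside the 13.1% to 25.9% of the other groups, and a single library excludes nothing. Loss of short inserts cannot be told apart either. There was no trend with length among 1229 other features up to 300 nt (Spearman 0.0397), under the bound set beforehand, but that bound was wrong: it used the length of the annotated feature, not of the insert, and left out miRNA, the short class that fell. A difference between the RNA samples of G8, technical or biological, stays open and was not tested.

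With TMM scaling nc886 was lower in A4, E4 and G8 than in A7 without PNK. Scaling alone is argued against as the cause for A4: with factors from miRNA alone A4 minus A7 was still -2.01, though no longer past the threshold (adjusted p = 0.182, with a wider spread under that scaling). For G8 the direction turns with it (A7 minus G8 -0.36, from 1.91). That turn cannot decide the G8 part, since miRNA factors take up the low miRNA of G8 libraries 1 and 2. They move the median of all features in A7 against G8 by -1.87. A difference in the total amount of nc886 and one in its RNA ends cannot be told apart: A7 minus the mean of the others was 2.54 without PNK and 0.66 with it, a difference of 1.88 (SE 0.427) that missed the threshold over 10811 features (edgeR, adjusted p = 0.156; 1 feature passed). The vault sum, which includes nc886, passed its own interaction test over the families (adjusted p = 0.0108), which goes against an equal difference in both arms, but it holds other vault RNAs too. A preparation axis of the minus-PNK libraries cannot be told apart either, since nc886 followed the second principal component at Spearman 0.607 over 15 libraries, between the bounds set for a trend and for none. The labels do not say whether the THP-1 groups differ in the Pol III subunit targeted, and an effect of the subunit stays open and untested.

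Other groupings of the same libraries were tested for the counts of calls. For the test across the 4 THP-1 groups, 1 of 100 groupings, the real one, gave as many calls in each arm: 575 against 44 in the highest other without PNK and 1890 against 522 with it. Some groups correlated by number without PNK, so 100 groupings that keep 1 library of each number in each group were fitted as well. The highest other gave 7 against 575, and with number as a block 5 against 421. Chance is an unlikely source of these counts, though only 100 groupings of each kind were fitted. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Against the libraries labelled mock without PNK the real and the highest other counts were 24 and 105 for A4, 7 and 0 for A7, 77 and 29 for E4, and 490 and 542 for G8. For A4 and G8, 2 of the 10 splits, the real one and 1 other, gave at least the real count: the split that sets A4 libraries 1 and 2 with mock library 3 apart calls several times the real count, which points to a structure of these samples, and that of G8 libraries 1 and 2 with mock library 3 sets the low-miRNA libraries of G8 apart. Libraries of A7 and mock with the same number correlated, and the real split parts all 3 same-numbered pairs. The other splits called 0 whether they part 3 such pairs or 1. The same held for A4 with E4 and A4 with G8, which also correlated by number. With PNK the counts were 1022 and 0 for A4, 454 and 13 for A7, 724 and 0 for E4, and 504 and 300 for G8. For the pairs the highest other was 0 in each, against 214 (A4 and A7), 16 (A4 and E4), 417 (A4 and G8), 2 (A7 and E4), 470 (A7 and G8) and 393 (E4 and G8) without PNK and 1159, 813, 1291, 8 and 951 with it, except A7 and G8 with PNK, at 709 and 3. For plus against minus PNK they were 6432 and 0.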

How the results depend on the processing

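The alternatives for the comparisons with the libraries labelled mock, for the interaction and for the pairs (except scaling and leave-one-out of their family sums), every deposited row, and the removal of G8 libraries 1 and 2 were chosen after seeing the data. Of the alternatives planned, those for the THP-1 groups against con and for the POLR3G oligonucleotide against control, and plus against minus PNK in con, were not run. Unless a cause is given, the cause was not tested.

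With factors from miRNA alone, 54 of the called family and isotype sums kept direction and threshold, 60 lost the threshold and 40 reversed. Among named genes 46 kept both, 17 lost the threshold and 5 reversed. Counts of calls moved to 6 (A4), 8 (E4) and 1021 (G8) against the libraries labelled mock without PNK, to 3866 (A4), 4222 (A7), 4637 (E4) and 310 (G8) with it, to 1018 and 6306 across the THP-1 groups without and with PNK, and to 2 for the interaction. In plus against minus PNK these sums reversed: 18S, 28S and 5.8S rRNA to 7.85, 5S rRNA 6.44, 7SL 7.66, 7SL pseudogenes 7.90, C/D snoRNA 1.79, H/ACA snoRNA 3.48, nuclear tRNA 6.61, Pol II snRNA 7.50, RMRP 3.6, scaRNA 2.89, snaR 5.01, U6atac 7.39, Y RNA pseudogenes 5.66 and Y RNA 5.53. The setting's own construction shows the cause, since it sets the typical fall of miRNA itself to 0.

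Factors from miRNA alone take up the low miRNA share of G8 libraries 1 and 2. Turns in comparisons with G8 are therefore partly built into that setting. Without PNK, miRNA factors reversed, in G8 against the libraries labelled mock, vault RNA to 1.12, nc886 0.83, RNY1 0.87, Y RNA pseudogenes 0.74 and tRNA-Met 0.18. In A4 against G8 they reversed Y RNA to -1.02, Y RNA pseudogenes to -0.33 and RNY5 to -0.40. In A7 against G8 they reversed nuclear tRNA to -1.51, vault RNA to -0.71, nc886 to -0.36 and Y RNA pseudogenes to -1.01, and in E4 against G8 Y RNA pseudogenes and RNY1, both to -1.20. With PNK they reversed, in A4 against the libraries labelled mock, 18S, 28S and 5.8S rRNA to -0.34, mitochondrial rRNA to -0.37 and mitochondrial tRNA to -0.17; in A7, 7SK to -0.24; and in E4, H/ACA snoRNA to -0.03, mitochondrial rRNA to -0.53 and mitochondrial tRNA to -0.46. In A4 against G8 they reversed C/D snoRNA to -0.67, H/ACA snoRNA to -0.06, mitochondrial rRNA to -0.81, mitochondrial tRNA to -0.40 and Y RNA to -0.74, in A7 against G8 Y RNA to -0.83 and Y RNA pseudogenes to -0.67, and in E4 against G8 C/D snoRNA to -0.78, mitochondrial rRNA to -1.08 and mitochondrial tRNA to -0.81.

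With library totals alone, 71 family and isotype sums kept direction and threshold, 65 lost the threshold and 18 reversed; of the named genes in plus against minus PNK 4 kept both, 3 lost the threshold and 4 reversed. Reversed in plus against minus PNK were 18S, 28S and 5.8S rRNA (3.17), 5S rRNA (1.78), 7SL (2.99), 7SL pseudogenes (3.2), nuclear tRNA (1.88), Pol II snRNA (2.80), snaR (0.33), U6atac (2.69), Y RNA (0.81), Y RNA pseudogenes (0.95), RNY3 (2.11), RNY4 (1.16), VTRNA1-1 (2.55) and VTRNA1-2 (1.54). In A4 with PNK 18S, 28S and 5.8S rRNA and mitochondrial rRNA both went to -0.05. In A7 against G8 without PNK 7SK pseudogenes went to 0.04, 7SL pseudogenes 0.25, RMRP 0.14 and U6 0.03, and in G8 against the libraries labelled mock without PNK tRNA-iMet and tRNA-Tyr to -0.24.

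DESeq2 called 86 (A4), 39 (A7) and 165 (E4) features against the libraries labelled mock without PNK, and its likelihood ratio test 913 across the THP-1 groups without PNK. DESeq2 size factors in edgeR gave 5 for A4 without PNK. With every deposited row the counts were 132 (A4), 3 (A7) and 1252 (G8) without PNK and 4652 (A4), 3377 (A7), 4716 (E4) and 3035 (G8) with it, 1845 and 11650 across the THP-1 groups and 17561 for plus against minus PNK, with many more features tested. With no filter they were 71 (A4), 35 (E4) and 259 (G8) without PNK and 10494 for plus against minus PNK, where 18S, 28S and 5.8S rRNA (0.53), 7SL (0.38), 7SL pseudogenes (0.57), Pol II snRNA (0.19) and U6atac (0.08) reversed. A fit of the 6 libraries alone gave 2 (A4), 36 (A7), 158 (E4) and 34 (G8) without PNK and 172 (G8) with it, from fewer samples. Camera with an estimated correlation called 11 lists, against 106 with the preset one.

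Without G8 libraries 1 and 2 the calls of G8 against the libraries labelled mock were 183 without PNK and 178 with it, and 3 families passed the interaction. Pol II snRNA reversed to -0.11 without PNK, and 39 of 66 family sums with G8 lost the threshold. Replicate number as a block gave 4 (A4) and 0 (A7) calls against the libraries labelled mock without PNK, and 26 family sums and 11 named genes lost the threshold. Among the comparisons whose libraries correlated by number, the block changed no other call named in the report.

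Leaving out 1 library at a time gave 0 to 44 calls for A4, 0 to 0 for A7, 5 to 59 for E4 and 202 to 1039 for G8 against the libraries labelled mock without PNK. With PNK it gave 569 to 994 for A4, 144 to 394 for A7, 385 to 689 for E4 and 257 to 868 for G8. The range was 247 to 1296 and 1465 to 2488 across the THP-1 groups, 5134 to 7454 for plus against minus PNK, 112 to 152 for the family sums (139) and 5 to 13 for the interaction. Of the fits, 642 for family and isotype sums kept the call and 282 lost it, and for named genes 409 and 119; none reversed. At this depth 4-fold changes were recovered better than 1.5-fold ones in every simulated comparison.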

Other observations

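The tests in this part were chosen after the result was seen. Counts summed over the copies of some tRNA isotypes were called although the nuclear tRNA sum was not called against the libraries labelled mock. Without PNK elongator tRNA-Met was 53.2 ± 9.34 CPM in A4 and 56.1 ± 2.64 in E4 against 224 ± 28.3 (log2 -2.08, SE 0.263, adjusted p = 2.31e-05, and -2.0, adjusted p = 3.51e-05; edgeR on the sums), without any 1 of the 6 libraries and with library totals and miRNA factors as well. In G8 it fell by 1.26 (adjusted p = 0.00207), which ended without G8 libraries 1 and 2 (-0.61) and turned to 0.18 with miRNA factors. In A7 it was at -0.90 (adjusted p = 0.0225), a call lost without any 1 library (adjusted p = 0.0574 to 0.122), with library totals (-0.62) and with miRNA factors (adjusted p = 0.345). Initiator tRNA-iMet went both ways: it was 0.61 higher in A7 (adjusted p = 0.00303), 0.42 in E4 (0.0131) and 0.32 in G8 (0.0426), and in A4 it was lower (-0.41, 0.0149). With miRNA factors the A7, E4 and A4 calls were lost (adjusted p = 0.803, 0.716 and 0.97), and the G8 value was 2.15; with library totals G8 turned to -0.24. With 1 library left out, 6 of 6 fits kept the A7 call, 5 the E4 call, 2 the A4 call and 1 the G8 call. Whether the isotypes differ from each other was not tested.

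With PNK tRNA-Tyr was higher than in the libraries labelled mock in A4 (log2 1.35, adjusted p = 0.00100), A7 (1.36, adjusted p = 0.000977) and E4 (1.92, adjusted p = 2.7e-05), by edgeR, without any 1 of the 6 libraries. With miRNA factors the A4 and A7 calls ended (0.51 and 0.39), and with library totals the A4 call did (0.77). These groups share the 3 mock libraries, so the rises are not independent of each other. tRNA-iMet in A4 with PNK was at 3.47 (adjusted p = 0.0167) and rests on A4 library 2, at 0.76 without it; the call was also lost without mock library 3 (adjusted p = 0.0591), with library totals (adjusted p = 0.149) and with miRNA factors (adjusted p = 0.0774).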
